A study of Mus musculus with 7 samples.

How the data were processed

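RNA of 7 samples of EGFP-positive, flow-sorted glioma cells was measured, 4 secondary and 3 tertiary gliomas. Per the labels' protocols, total RNA was extracted with Trizol, and 30 ng of it was amplified to cDNA with the NuGEN Ovation Pico WTA System V2 and labelled with biotin through the Encore Biotin Module. The deposited table holds log2 expression values, 1 per probe and array, made by the authors with RMA (background correction, quantile normalization and summary of probes) per the submitters' processing notes. The RMA version and software are not given in the sources used here, and the log base was taken from the values. RMA equalises the arrays, so a change shared by most genes would be hidden, and it compresses differences of dim probes. Scanner files were not used here, and detection calls, scan dates and slides were not analysed here, so no batch was tested. All columns of the table belonged to the 7 samples.

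Probes were named through the platform annotation given for this table. Of 45101 probes, 34945 had 1 gene symbol, 932 had several and 9160 had none listed, and 64 were control probes. Of the named probes, 34741 had a gene identifier found in the gene table of assembly GRCm38.p6, and 0 symbols needed updating. Probes with several symbols or none were left out, and 18193 genes remained. A gene was represented by its probe with the highest mean over the 7 arrays. Genes whose probe had a mean below the 25th percentile of all probes, a log2 value of 3.99, were left out, and 14453 genes were tested. The array build is not given in the sources used here, so no coordinates are reported.

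Groups came from the labels. Tertiary gliomas were compared with secondary gliomas using limma 3.58.1 (lmFit and eBayes with default settings) in R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested and an adjusted p under 0.05 as the threshold. Log2 fold changes are tertiary minus secondary, with the standard error from limma. No covariate was used. Gene lists for 40 pathways and cell types were fixed before the data were examined. They held 692 distinct genes, of which 627 matched a probe with 1 symbol and 557 were tested. The 38 lists with at least 5 tested genes were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. The count of called members was also adjusted over the list alone. The red blood cell and sex-linked lists had too few tested genes. Similarity between samples was 1 minus Pearson's r over the genes tested, with an exact permutation test over all 35 ways to choose 3 of the 7 samples. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 from tables read with pandas 2.3.3.

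The genes named in the text were chosen by a rule fixed before the data were examined. It takes the 12 called genes with the largest and the 12 with the most negative log2 fold change among those whose groups do not overlap, passing over predicted genes and clones. It adds up to 4 called members of each list by lowest p, or up to 2 with the lowest p where none was called. A fixed set of 12 genes is always given, of which Trp53 was not analysed here. Genes named outside the rule are said to be.

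The steps were tested on simulated data with the spread of these arrays. Over 14453 genes, tertiary against secondary, 41% of 100 genes changed by log2 1 and 87% of 100 changed by log2 2 were recovered. There were 2 false calls, and no unchanged list was called. Fewer genes were changed there than the 1066 called in the real arrays, and rises and falls were equally many. The recovered shares may therefore differ in the real comparison. The simulated genes varied independently of each other, so the list result does not cover lists whose genes move together. In the real arrays the estimated inter-gene correlation was 0.93 in the G2/M list. Pairs of arrays shared the same value at no more than 5.39% of probes, so no sample was counted as a repeat of another. The alternatives were the mean of all probes of a gene, no filter on dim probes or a filter at the 50th percentile, quantile normalization or median centring of the deposited values, trended and robust variances, array weights, a replicate block, every probe tested on its own, an adjusted p under 0.10, variances for each gene on its own, and leaving out each sample in turn. For the distances they were Euclidean distance and the 1000 genes of largest variance. Alternatives added after seeing the data were the comparison without the genes of 10 immune lists and the comparison without both secondary glioma 3 and tertiary glioma 1.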

Results

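Genome-wide mRNA levels were measured on Affymetrix mouse arrays in glioma cells that had been passaged from mouse to mouse. The starting tumours were gliomas of early onset and low grade, induced in C57/Bl6 mice by overexpressing the growth factor PDGF-B together with the green fluorescent protein EGFP. Cells of such primary tumours were grafted into NOD/SCID mice, which lack functional B and T lymphocytes, and gave the secondary gliomas (n = 4). Cells of a secondary glioma were grafted again into NOD/SCID mice and gave the tertiary gliomas (n = 3). In all 7 cases the tumour was dissociated with trypsin and EGFP-positive cells were collected by flow sorting before RNA was extracted. The labels call the samples of a group biological replicates but do not say which primary tumour, donor glioma or host each came from, so p-values here measure the spread between these samples. The deposited log2 values had medians between 5.57 and 5.64 on the 7 arrays, and the number of arrays limits the precision.

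The first comparison asks which genes differ between gliomas of the second transplant and those of the first, in a host without adaptive immunity. Of 14453 genes tested, 915 were lower and 151 were higher in tertiary gliomas. Siglecf, a sialic acid-binding lectin of myeloid cells, had a log2 fold change of -5.55 ± 0.64 (SE, n = 4 and 3; adjusted p = 0.00141). It was at -6.34 without tertiary glioma 1 and -4.81 without tertiary glioma 3, and its tertiary values of 5.74, 4.06 and 2.69 reached below the filter on dim probes. Ptprc, the pan-leukocyte surface phosphatase, dropped from a log2 level of 10.23 ± 0.27 (SD) to 4.86 ± 0.69 (log2 fold change -5.37, adjusted p = 8.13e-05).

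The other genes with the largest falls were Plau, the urokinase plasminogen activator (log2 fold change -5.53 ± 0.23 SE), the neutrophil chemokine Cxcl2 (-5.53 ± 0.38), the organic anion transporter Slco2b1 (-5.46 ± 0.29), Cd34 (-5.40 ± 0.31) and the prostaglandin receptor Ptger4 (-5.38 ± 0.28). They also included AI467606 (-5.18 ± 0.39), the leukocyte surface protein Cd48 (-5.17 ± 0.34), the matrix protein nephronectin, Npnt (-5.09 ± 0.47), Ms4a6b (-5.07 ± 0.38) and the integrin subunit Itgb5 (-5.04 ± 0.32). All 12 kept their call in each of the fits that left out 1 sample. Markers of microglia and macrophages moved with them, with a list mean of 10.3 ± 0.34 (SD) in secondary and 6.27 ± 0.42 in tertiary gliomas. In 5 of the 12 (AI467606, Cd48, Ms4a6b, Npnt and Ptger4) the tertiary mean lay below the filter on dim probes, a log2 value of 3.99, and no detection calls were used. With all probes of a gene averaged, Npnt was at -2.64, Slco2b1 at -3.36, Ms4a6b at -3.44 and AI467606 at -3.77, each still called. The Itgb5 and Slco2b1 probes are of a kind that can bind related transcripts.

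**Figure D1:**
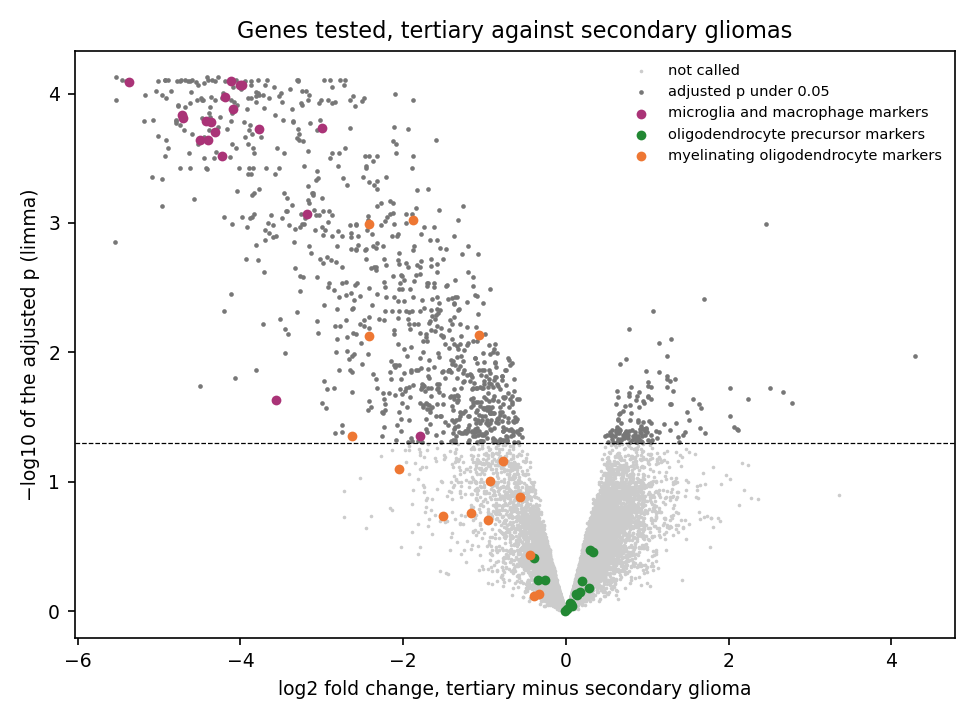
Log2 fold change (tertiary minus secondary glioma) against −log10 of the adjusted p for the 14453 genes tested with limma, n = 4 secondary and 3 tertiary gliomas; the dashed line marks an adjusted p of 0.05. The 915 genes called lower reach log2 fold changes beyond -5, while most of the 151 called higher stay below 2.

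Among the 1066 called genes, 833 changed by at least 1 on the log2 scale, 779 of them lower and 54 higher. The median log2 fold change was -1.96 over the genes called lower, 0.90 over those called higher and 0.09 over all genes tested. At an unadjusted p under 0.05 there were 3444 genes. The values of the 2 groups did not overlap in any of the 1066 called genes, and did not overlap in 21.9% of all genes tested, where chance gives 5.71%. The total became 1857 without tertiary glioma 1, 647 without tertiary glioma 2 and 653 without tertiary glioma 3, and the number changed by at least 1 became 1255 without tertiary glioma 1. With variances estimated for each gene on its own, 210 genes were called, 205 of them lower.

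Genes higher in tertiary gliomas were led by Cnpy1, a regulator of fibroblast growth factor signalling, at 4.29 ± 0.73 (log2 fold change ± SE, n = 4 and 3, adjusted p = 0.0107), or 5.27 without tertiary glioma 1 and 3.72 without tertiary glioma 2. En2, a homeobox gene of the midbrain and hindbrain, rose by 2.01 ± 0.43 and Pou4f1, a transcription factor of sensory neurons, by 2.46 ± 0.27 (adjusted p = 0.00103). Genes of the extracellular matrix among the 12 largest rises were the collagens Col18a1 (2.23 ± 0.45) and Col6a1 (1.71 ± 0.40) and the hyaluronan synthase Has2 (1.69 ± 0.24, adjusted p = 0.00385). The stress-induced pseudokinase Trib3 rose by 2.02 ± 0.39 and the secreted glycoprotein stanniocalcin, Stc2, by 2.51 ± 0.48. The Trib3 probe is of a kind that can bind related transcripts. The remaining 4 were the ubiquitin ligase Mid2 (2.77 ± 0.57), the calcium channel subunit family member Cacng5 (2.11 ± 0.48), the mitochondrial carrier Slc25a24 (2.06 ± 0.46) and Skida1 (1.66 ± 0.35).

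The rises depended on single samples more than the falls. The 151 genes called higher became 56, 77, 68 and 70 without secondary gliomas 1 to 4 in turn, and 781, 27 and 43 without tertiary gliomas 1 to 3. Pou4f1 and Has2 kept their call in each of these fits. Without tertiary glioma 2 the adjusted p was 0.0800 for Mid2, 0.0798 for Stc2, 0.0986 for Col18a1, 0.124 for Cacng5, 0.140 for Slc25a24, 0.0848 for Trib3, 0.124 for En2 and 0.111 for Skida1. Without tertiary glioma 3 it was 0.0524 for Cnpy1, 0.0501 for Mid2, 0.0817 for Col18a1, 0.127 for Cacng5, 0.127 for Slc25a24, 0.0544 for Trib3, 0.115 for En2, 0.104 for Col6a1 and 0.0777 for Skida1. Leaving out secondary gliomas also ended calls, with adjusted p of 0.0507 (Mid2), 0.0510 (Stc2), 0.0509 (Trib3), 0.0540 (En2), 0.0776 (Col6a1) and 0.0671 (Skida1) without secondary glioma 1. Those without secondary glioma 2 were 0.0641 (Col18a1), 0.0727 (Cacng5), 0.0632 (Slc25a24) and 0.107 (Col6a1). Without secondary glioma 3 they were 0.0633 (Col18a1), 0.0777 (Cacng5), 0.0916 (Slc25a24) and 0.109 (Col6a1), and without secondary glioma 4 they were 0.0641 (Col18a1), 0.0980 (Cacng5), 0.0579 (Trib3), 0.0694 (En2) and 0.0832 (Col6a1). With all probes averaged, Skida1 was at 1.05 (adjusted p = 0.0718), and without the dim filter the adjusted p was 0.0558 for Cacng5, 0.0583 for Col6a1 and 0.0530 for Slc25a24. Secondary glioma 3 had the lowest value of all 7 samples in 7 of the 12 genes, and the secondary means of Mid2, Skida1 and Slc25a24 lay below the dim filter.

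**Figure D2:**
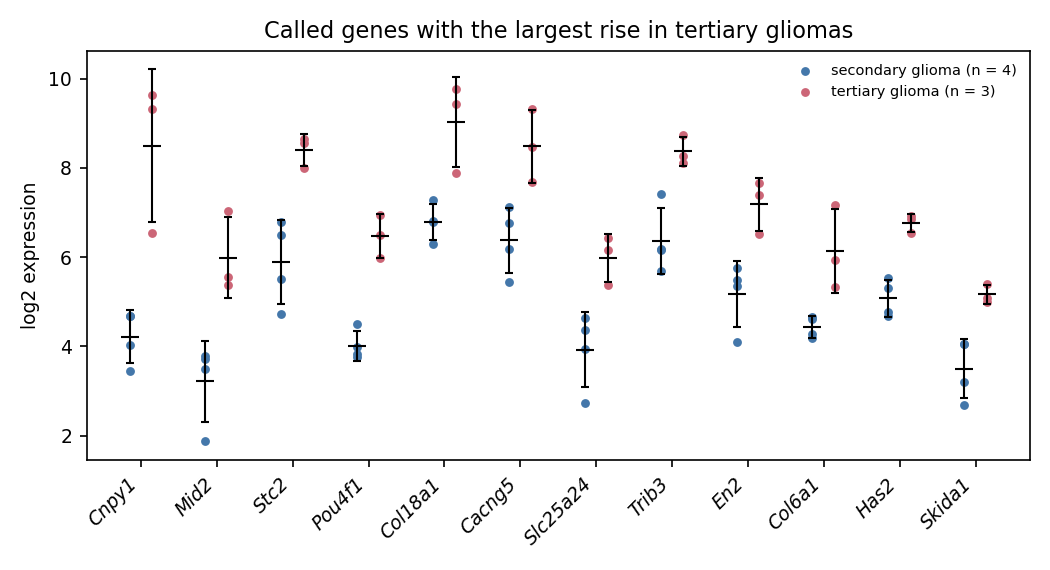
Log2 expression of the 12 called genes with the largest rise in each glioma (points; 4 secondary, 3 tertiary), with the mean and SD of each group. The genes were picked among those whose groups do not overlap, and the tertiary values of Cnpy1 range from 6.54 to 9.64.

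The second comparison asks whether gene groups chosen before the data were examined moved together. Markers of microglia and macrophages fell as a group: 19 of 19 tested were lower, and 19 adjusted over the list alone. Their median log2 fold change was -4.19, with Cd68 at -3.97 ± 0.24 (SE), the immunoglobulin receptor chain Fcer1g at -4.12 ± 0.24 and the lipid receptor Trem2 at -4.0001 ± 0.24. The Trem2 probe can bind related transcripts, and with all probes averaged its log2 fold change was -2.01. The list had an adjusted p of 1.21e-29 in limma's camera and an adjusted p of 0.228 with an estimated correlation. Granulocyte and monocyte markers followed, with 3 of 7 lower (4 adjusted over the list alone, median -1.47), the colony-stimulating factor receptor Csf3r at -4.38 ± 0.32 and the calprotectin subunits S100a9 at -3.45 ± 0.53 and S100a8 at -3.42 ± 0.54. The median was -0.45 without the dim filter and -2.44 with all probes averaged, and the S100a8 probe can bind related transcripts. That list had an adjusted p of 0.000216 and an adjusted p of 0.228 with an estimated correlation. None of the 6 tested markers of lymphocytes and natural killer cells passed (median -0.03, adjusted p = 0.620), with Cd79b at -0.34 ± 0.26 and perforin, Prf1, at 0.12 ± 0.16.

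Of the 38 lists tested, 15 were called, 11 lower and 4 higher. None was called with an estimated correlation, where the lowest adjusted p was 0.216, and fry called 12, all but the DNA repair, oxidative phosphorylation and G2/M lists. The 4 lists called higher became 8, 1 and 2 without tertiary gliomas 1, 2 and 3. Of the 35 splits of the 7 samples into 4 and 3, 10 gave 15 or more called lists, the real split included.

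Genes of antigen presentation fell. In the MHC class II list 8 of 11 were lower (9 adjusted over the list alone, median -2.90), led by the invariant chain Cd74 (log2 fold change -4.68 ± 0.34 SE), H2-Eb1 (-3.33 ± 0.42), H2-Ob (-3.10 ± 0.32) and the protease Ctss (-2.90 ± 0.25). Its adjusted p was 2.49e-08, and the adjusted p was 0.238 with an estimated correlation. In the MHC class I list 9 of 15 were lower (11 adjusted over the list alone, median -0.89), with the peptide-loading protein Tapbp at -2.51 ± 0.17, H2-M3 at -2.33 ± 0.28, H2-D1 at -1.84 ± 0.19 and H2-K1 at -1.78 ± 0.20. Its adjusted p was 5.30e-09, and the adjusted p was 0.228 with an estimated correlation. The light chain B2m fell by 0.69 ± 0.14 on the log2 scale (adjusted p = 0.0229) from a high level of 12.49 ± 0.08 (SD). Its adjusted p was 0.0657, 0.0527 and 0.0710 without secondary gliomas 2, 3 and 4, and 0.0838 and 0.0708 without tertiary gliomas 2 and 3. With all probes averaged H2-D1 was at -1.01. The probes of H2-D1 and H2-K1 can bind related transcripts, and whether the H2 probes read the alleles of C57/Bl6 tumour cells and NOD host cells alike is not given in the sources used here, which limits the H2 fold changes. Microglia and macrophage markers were lower in the same samples at a median log2 fold change of -4.19.

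Secreted and innate immune genes fell as well. Of the cytokines and chemokines, 13 of 21 were lower (14 lower and 1 higher adjusted over the list alone, median -2.11), with Cxcl2 at -5.53, interleukin Il1a at -4.53 ± 0.31, Ccl4 at -4.04 ± 0.29 and Tgfb1 at -3.47 ± 0.26. The list's adjusted p was 1.45e-12, and the adjusted p was 0.216 with an estimated correlation, and the median was -1.30 without the dim filter. Of the complement genes, 6 of 10 were lower (6 adjusted over the list alone, median -2.29), including the receptors C3ar1 (-4.63 ± 0.33) and C5ar1 (-3.78 ± 0.37) and the initiating subunits C1qa (-4.43 ± 0.34) and C1qc (-4.19 ± 0.28). Its adjusted p was 1.11e-08, and the adjusted p was 0.228 with an estimated correlation, and 3 of its tested genes are also in the microglia list. The complement median was -1.09 without the dim filter and -3.98 with a filter at the 50th percentile. In the type I interferon list 9 of 25 were lower (12 adjusted over the list alone, median -0.54), with Trim30a at -4.53 ± 0.27, Oas1a at -1.88 ± 0.13, Mx1 at -1.80 ± 0.23 and Rsad2 at -1.12 ± 0.15. Its adjusted p was 7.00e-09, and the adjusted p was 0.274 with an estimated correlation. The microglia and macrophage markers were lower in the same libraries at a median log2 fold change of -4.19.

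Of 12 immune checkpoint and evasion genes tested, 4 fell and 1 rose (5 lower and 1 higher adjusted over the list alone; median -0.06). The inhibitory receptor Havcr2 changed by -4.31 ± 0.29, Tgfb1 by -3.47, the ectonucleotidase Entpd1 by -1.65 ± 0.24 and Cd274, which encodes the ligand PD-L1, by -1.51 ± 0.24 (adjusted p = 0.00754). The lectin Lgals1, named after its value was seen, was higher by 1.28 ± 0.29, with an adjusted p of 0.0988, 0.0865 and 0.0812 without secondary gliomas 2, 3 and 4 and of 0.147 and 0.142 without tertiary gliomas 2 and 3. The list's adjusted p was 0.0357, but 0.0668 without secondary glioma 2 and 0.0556 without tertiary glioma 2, and the adjusted p was 0.228 with an estimated correlation. The checkpoint median was -0.0353, -0.21 and -0.10 without secondary gliomas 1, 3 and 4, -0.15, -0.11 and -0.30 without tertiary gliomas 1, 2 and 3, and -0.75 with a filter at the 50th percentile. In the interferon gamma list 3 of 13 were lower (4 adjusted over the list alone): the transcription factor Irf8 (-3.36 ± 0.34), Cd274 and the chemokine Cxcl10 (-2.75 ± 0.61). The list was not called (adjusted p = 0.147), and its median of 0.02 differs in sign from its mean of -0.52 and from the test. The call of Cxcl10 was lost without any of secondary gliomas 1 to 4 (adjusted p = 0.0661, 0.0712, 0.101 and 0.0932) and without tertiary gliomas 1 and 3 (0.0597 and 0.0638), and without the dim filter (0.0528). Its log2 fold change was -3.48 without tertiary glioma 2 and -2.02 without tertiary glioma 3. Microglia and macrophage markers moved in the same direction at a median log2 fold change of -4.19.

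**Figure D3:**
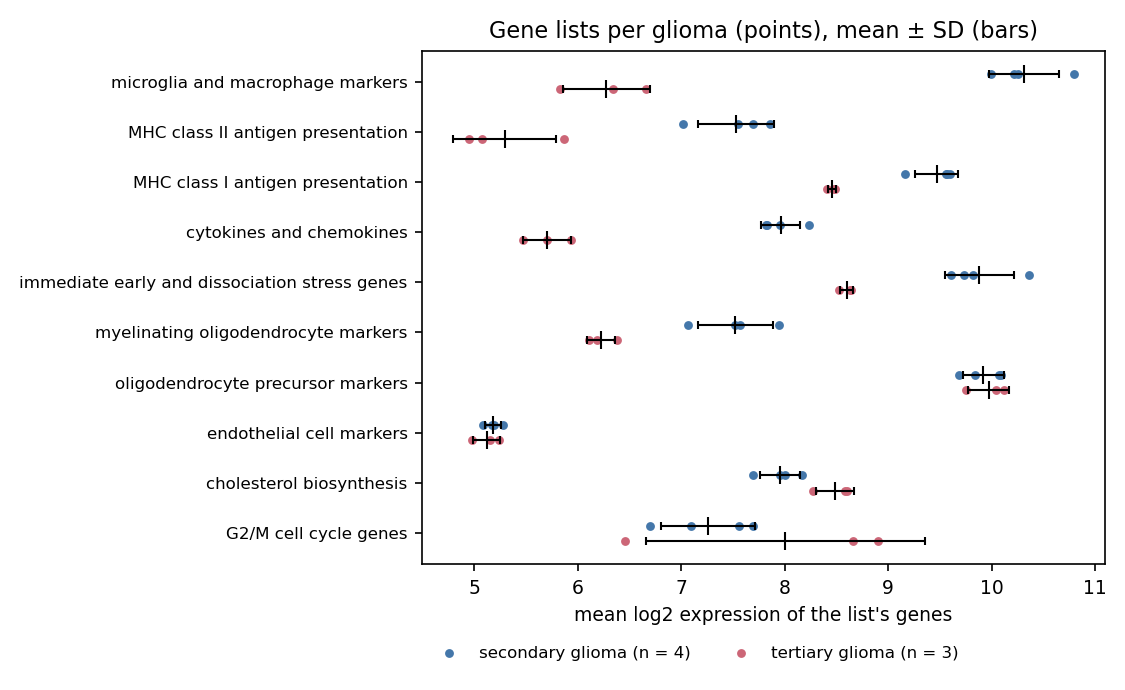
Mean log2 expression of the genes of 10 lists in each glioma (points), with the mean (tick) and SD (bar) of the 4 secondary and 3 tertiary gliomas. Microglia and macrophage markers average 10.3 in secondary and 6.27 in tertiary gliomas, while oligodendrocyte precursor markers average 9.92 and 9.97.

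Immediate early genes, which respond within minutes to stimulation and to tissue dissociation, were lower in 10 of 24 cases (17 adjusted over the list alone, median -1.03). The transcription factor Atf3 changed by -3.81 ± 0.26 (SE), Klf2 by -3.03 ± 0.32, the antiproliferative gene Btg2 by -2.93 ± 0.32 and the mRNA-destabilising protein Zfp36 by -2.77 ± 0.15. The list mean was 9.88 ± 0.33 (SD) in secondary gliomas, where secondary glioma 3 reached 10.4, and 8.60 ± 0.06 in tertiary gliomas. The list's adjusted p was 1.45e-12, and the adjusted p was 0.230 with an estimated correlation, and microglia and macrophage markers were lower in the same samples at a median log2 fold change of -4.19.

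The unfolded protein response list went both ways, with 2 of 19 higher and 2 lower, also adjusted over the list alone, and was not called (median 0.13, adjusted p = 0.703). Trib3 (2.02 ± 0.39) and Ddit3 (0.97 ± 0.23), a pair of genes induced under endoplasmic reticulum stress, rose, while Atf3 and the degradation factor Edem1 (-1.91 ± 0.26) fell. Of the 2 Ddit3 probes above the dim filter only 1 had that sign, and with the probes averaged its log2 fold change was 0.39 (adjusted p = 0.270). The call was also lost without the dim filter (0.0550) and with array weights (0.0619). Its adjusted p was 0.0940, 0.0949 and 0.0764 without secondary gliomas 1, 3 and 4, and 0.0750, 0.136 and 0.0804 without tertiary gliomas 1, 2 and 3. The call of Trib3 was lost without secondary gliomas 1 (0.0509) and 4 (0.0579) and tertiary gliomas 2 (0.0848) and 3 (0.0544).

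In the list of mesenchymal and extracellular matrix genes, 6 of 22 fell and 1 rose (8 lower and 2 higher adjusted over the list alone; median -0.26). The galectin Lgals3 changed by -3.89 ± 0.42, Tgfbi by -2.63 ± 0.51, the matrix protein Sparc by -2.58 ± 0.41 and fibronectin, Fn1, by -2.24 ± 0.45. The hyaluronan receptor Cd44, named after its value was seen, rose by 1.49 ± 0.31, with an adjusted p of 0.0655, 0.0537, 0.0811 and 0.0801 without secondary gliomas 1 to 4 and of 0.0887 without tertiary glioma 3. The list's adjusted p was 0.0115, and the adjusted p was 0.228 with an estimated correlation. The Fn1 call was lost without secondary gliomas 2 (adjusted p = 0.0656) and 3 (0.0566) and tertiary glioma 3 (0.0694), and that of Tgfbi without secondary gliomas 2 (0.0624) and 3 (0.0621) and tertiary glioma 3 (0.0537). Without tertiary glioma 1 Tgfbi was at -1.93 and the list median at -0.62, and the median was -0.41 without secondary glioma 4. The Tgfbi probe can bind related transcripts. Of the 3 Sparc probes above the dim filter, 2 had the same sign, averaging all of its probes gave -1.61, and microglia and macrophage markers were lower at a median log2 fold change of -4.19 in these samples.

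Markers of oligodendrocyte precursors, proneural glioma and neural progenitors did not pass. Of 15 oligodendrocyte precursor markers none was called, also adjusted over the list alone, and the median was 0.07 (adjusted p = 0.859). Pdgfra, the receptor for PDGF, had a log2 fold change of 0.05 ± 0.14 (SE, n = 4 and 3), the proteoglycan Cspg4 0.07 ± 0.28, Olig2 0.17 ± 0.24, Sox10 0.30 ± 0.17 and versican, Vcan, 0.34 ± 0.20. The mean level of Pdgfra was 10.96 ± 0.17 (SD) in secondary and 11.01 ± 0.11 in tertiary gliomas. Of 15 proneural glioma genes none passed (median 0.17, adjusted p = 0.477), with Sox2 at 0.80 ± 0.30 (adjusted p = 0.164) and Ncam1 at 0.54 ± 0.24. Of 13 neural stem cell and progenitor genes none passed (median 0.52, adjusted p = 0.0559), with Sox11 at 1.24 ± 0.35 and nestin, Nes, at 1.30 ± 0.42.

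Genes of mature oligodendrocytes fell. In the myelinating oligodendrocyte list 5 of 15 were lower (9 adjusted over the list alone, median -1.07), and all 15 had a negative log2 fold change. The structural myelin genes Mag (-2.42 ± 0.38 SE) and Mog (-2.42 ± 0.26), the N-acetylaspartate-cleaving enzyme Aspa (-1.88 ± 0.20) and Ppp1r14a (-1.07 ± 0.17) were among them. The other was Ermn (-2.62 ± 0.62), named after its value was seen, whose adjusted p was 0.0931, 0.0752, 0.110 and 0.109 without secondary gliomas 1 to 4 and 0.163 and 0.142 without tertiary gliomas 2 and 3, and whose log2 fold change was -3.47 without tertiary glioma 1. Mbp had a log2 fold change of -2.06 ± 0.58 that missed the threshold (adjusted p = 0.0796). The list's adjusted p was 2.49e-08, and the adjusted p was 0.228 with an estimated correlation, and the median of the microglia and macrophage markers was -4.19. Of 13 astrocyte markers none passed (median -0.37, adjusted p = 0.263), with Gfap at -0.45 ± 0.51, Aqp4 at -1.68 ± 0.69 and Aldh1l1 at -0.60 ± 0.21. Of 12 neuron markers none passed (median -0.00237, mean 0.21, direction up in the test, adjusted p = 0.787), with the tubulin Tubb3 at 1.81 ± 0.50 (adjusted p = 0.0763) and Map2 at 0.56 ± 0.22. Of the 3 Gfap probes above the dim filter, 2 had the same sign.

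Of the vascular and stromal markers, 2 passed. None of 11 endothelial markers passed (median -0.24, adjusted p = 0.446), with Cdh5 at -0.48 ± 0.15 and Vwf at 0.64 ± 0.21. Of 8 pericyte and mural cell markers 2 were lower, also adjusted over the list alone: Anpep (-1.88 ± 0.36) and the potassium channel regulator Abcc9 (-1.59 ± 0.37), with the list not called (median -0.16, adjusted p = 0.263). The Anpep call was lost without secondary glioma 4 (adjusted p = 0.0539) and tertiary gliomas 2 (0.0731) and 3 (0.0708), and the Abcc9 call without secondary gliomas 2 (0.0625) and 4 (0.0989) and tertiary gliomas 1 (0.0518), 2 (0.154) and 3 (0.129) and without the dim filter (0.0591). None of 9 fibroblast and meningeal markers passed (median -0.50, adjusted p = 0.220), with decorin, Dcn, at -1.30 ± 0.56 and Slc6a13 at -0.22 ± 0.15. None of 6 ependymal and choroid plexus markers passed (median -0.21, adjusted p = 0.391), with Folr1 at -0.52 ± 0.23. Transthyretin, Ttr, abundant in choroid plexus, lay at 10.1 and 9.22 in secondary gliomas 1 and 4 and between 5.14 and 6.14 in the other 5 samples.

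Cell cycle genes differed among the tertiary gliomas. All 21 G2/M genes tested had a positive log2 fold change (median 0.76), but none passed, also adjusted over the list alone. The list mean was 6.45 in tertiary glioma 1 against 8.66 and 8.90 in tertiary gliomas 2 and 3, and lay between 6.70 and 7.69 in the secondary gliomas. The median was 1.50, 0.45 and 0.35 without tertiary gliomas 1, 2 and 3, and 1.24 with array weights. Mki67 had a log2 fold change of 0.32 ± 0.50, Kif23 of 0.96 ± 0.54 and Bub1b of 0.94 ± 0.51. The list was called higher (adjusted p = 0.0367), with an adjusted p of 0.749 with an estimated correlation, and the call was lost without secondary gliomas 2 (0.176) and 3 (0.0741), tertiary gliomas 2 (0.348) and 3 (0.571), with arrays centred on their medians (0.0760) and with a filter at the 50th percentile (0.0543). Of 21 G1/S genes none passed (median 0.59, adjusted p = 0.0544), with the replication helicase subunit Mcm2 at 0.90 ± 0.36 and the chromatin assembly factor Chaf1b at 1.08 ± 0.40.

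Of 17 DNA repair genes none passed, also adjusted over the list alone, while the list was called higher (median 0.52, adjusted p = 0.0153, and adjusted p = 0.736 with an estimated correlation). The list mean was 6.24 in tertiary glioma 1, below the 6.27 to 6.51 of the secondary gliomas, against 7.44 and 7.18 in tertiary gliomas 2 and 3, and the G2/M list was likewise low in tertiary glioma 1, at 6.45 against 8.66 and 8.90. Without tertiary glioma 1 the DNA repair median was 0.91. Xrcc6, part of the end-joining complex, was at 0.80 ± 0.20 (adjusted p = 0.0553) and Brca2 at 1.02 ± 0.32. The call was lost without tertiary gliomas 2 (0.122) and 3 (0.0733) and with a filter at the 50th percentile (0.0762). Of 16 cell cycle inhibitors and p53 targets 1, Btg2, was lower, also adjusted over the list alone, and the list was not called (median -0.12, adjusted p = 0.263). The tumour suppressor Cdkn2a had a log2 fold change of 0.90 ± 0.43 (adjusted p = 0.243), and Trp53 was not analysed here.

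Enzymes of cholesterol synthesis were higher as a group (median 0.60). Of 19 tested, 2 rose, Cyp51 by 0.77 ± 0.15 (SE) and Fdps by 1.37 ± 0.33, and 11 rose adjusted over the list alone, while 17 had a positive log2 fold change. The list's adjusted p was 0.000253, and the adjusted p was 0.495 with an estimated correlation. The Cyp51 call was lost without secondary gliomas 1, 2 and 3 (adjusted p = 0.0507, 0.0647 and 0.0507) and tertiary gliomas 2 and 3 (0.0916 and 0.0890), and the Fdps call without secondary gliomas 1, 2 and 3 (0.0993, 0.0911 and 0.0967) and tertiary gliomas 2 and 3 (0.145 and 0.134). With all probes averaged Fdps was at 0.68 and lost its call (0.0546), as it did without the dim filter (0.0616).

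Of 25 subunits of oxidative phosphorylation none passed, also adjusted over the list alone, and 22 had a positive log2 fold change (median 0.22). Cytochrome c-1, Cyc1, was at 0.49 ± 0.18 and the ATP synthase subunit Atp5b at 0.49 ± 0.19. The list was called higher (adjusted p = 0.0246), with an adjusted p of 0.749 with an estimated correlation, had a median of 0.14 with array weights, and lost the call without secondary glioma 3 (0.0554), without tertiary glioma 2 (0.170) and with a filter at the 50th percentile (0.0575). Of 20 cytosolic ribosomal proteins none passed (median 0.15, adjusted p = 0.263), with Rplp0 at 0.38 ± 0.22 and Rpl8 at 0.34 ± 0.18. Of 16 glycolysis enzymes 1 rose, the phosphofructokinase Pfkp (0.71 ± 0.17, adjusted p = 0.0460), and none adjusted over the list alone (list median 0.17, adjusted p = 0.325). That call was lost without each of secondary gliomas 1 to 4 (0.0680, 0.116, 0.104 and 0.0890) and tertiary gliomas 2 and 3 (0.165 and 0.156), without the dim filter (0.0508) and with trended and robust variances (0.0550).

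Of 18 hypoxia response genes 1 rose, the oxidoreductase Ero1a (1.05 ± 0.20), and 1 fell, Ndrg1 (-1.77 ± 0.43), with 6 higher and 3 lower adjusted over the list alone. The list was not called (median 0.36, adjusted p = 0.528). The Ero1a call was lost without tertiary glioma 2 (adjusted p = 0.0811), and the Ndrg1 call without each of secondary gliomas 1 to 4 (0.108, 0.0790, 0.124 and 0.112), without tertiary gliomas 1 and 3 (0.0520 and 0.148) and with arrays centred on their medians (0.0573), quantile normalization (0.0514), trended and robust variances (0.0505) or no dim filter (0.0689). With all probes averaged Ndrg1 was at -1.07. The Ndrg1 probe can bind related transcripts.

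Few genes of the signalling lists passed. In the PDGF and MAPK list 2 of 19 were lower, also adjusted over the list alone: Pdgfb (-1.67 ± 0.25 SE) and the phosphatase Dusp5 (-1.08 ± 0.16). The list was not called (median 0.12, mean 0.00182, direction down in the test, adjusted p = 0.952), and whether the Pdgfb probe reads the transgene is not given in the sources used here. Of 16 angiogenesis factors 3 fell, Pdgfb, endothelin Edn1 (-1.30 ± 0.21) and Pdgfa (-0.98 ± 0.23), with 4 lower and 2 higher adjusted over the list alone (median 0.05, mean -0.03, direction down in the test, adjusted p = 0.612). The Pdgfa call was lost without secondary gliomas 1, 2 and 3 (0.0947, 0.0881 and 0.102), without tertiary gliomas 1 and 2 (0.0729 and 0.155) with arrays centred on their medians (0.0522), with all probes averaged (0.0553), without the dim filter (0.0530) and with array weights (0.0720).

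In the Hedgehog and BMP list the inhibitory signal transducer Smad7 (-2.59 ± 0.18) and Id2 (-1.09 ± 0.21) fell among 14 tested, 3 adjusted over the list alone, and the list was not called (median 0.09, mean -0.16, direction down in the test, adjusted p = 0.466). The Smad7 probe can bind related transcripts, and the Id2 call was lost without secondary glioma 2 (adjusted p = 0.0555) and tertiary gliomas 2 (0.0809) and 3 (0.0777). In the Notch list the receptor Notch2 fell (-2.03 ± 0.39), 1 of 16, with 1 lower and 1 higher adjusted over the list alone (median 0.03, mean -0.03, direction up in the test, adjusted p = 0.861). Its call was lost without secondary gliomas 2 (0.0584) and 4 (0.0513) and tertiary glioma 3 (0.0831), and with all probes averaged it was at -1.28. None of 16 Wnt pathway genes passed (median 0.22, adjusted p = 0.446), with Tcf7l2 at -0.77 ± 0.24 and Wnt5a at 0.76 ± 0.24. None of 11 imprinted and oncofetal genes passed (median 0.28, adjusted p = 0.612), with Hmga2 at 1.80 ± 0.81 and Peg10 at 0.34 ± 0.17. Microglia and macrophage markers were lower, with a median log2 fold change of -4.19, in the samples where Pdgfb, Smad7, Id2 and Notch2 fell.

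The third comparison asks whether gliomas of the same passage resembled each other more than those of the other passage. The mean distance between samples, 1 minus Pearson's r over the genes tested, was 0.122 between groups, 0.0367 within secondary and 0.0526 within tertiary gliomas. The distance between groups exceeded that within groups by 0.0798 (one-sided exact permutation p = 0.0286, the smallest that the 35 splits can give). Secondary gliomas 2 and 4 were the closest pair (r = 0.981) and secondary glioma 3 and tertiary glioma 3 the most distant (r = 0.825). The spread within tertiary gliomas minus that within secondary gliomas was 0.0159 (two-sided exact permutation p = 0.686), and became -0.00518 without tertiary glioma 1. The leading principal component held 62.4% of the variance and separated the groups, and the next held 14.6% and set tertiary glioma 1 apart. Leaving out 1 sample raised the exact p of the distance between groups to 0.0667 or 0.1, the smallest such designs allow.

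RNA quality was compared through the signal of 3' minus 5' control probes. For Actb the log2 difference was -0.37 ± 0.02 (SD, n = 4) in secondary and -0.32 ± 0.06 (n = 3) in tertiary gliomas (two-sided exact permutation p = 0.200). For Gapdh it was 1.90 ± 0.11 and 1.71 ± 0.23 (exact permutation p = 0.229).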

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

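Each result was screened in the 4 secondary gliomas for a sample whose gap to the nearest of the others, divided by the group's range, exceeded Dixon's critical value for 4 samples. Of 160 results 11 did so, where chance gives about 1 in 20, or 8. In 7 of the 11 the sample apart was secondary glioma 3. It had the highest value of Atf3 (11.04 against 10.00 to 10.10 in the others), Smad7 (8.14 against 7.504 to 7.543), Cd79b (4.95 against 3.95 to 3.98) and Folr1 (4.92 against 4.01 to 4.14). It had the lowest value of Cdkn2a (4.99 against 6.11 to 6.21) and Mid2 (1.87 against 3.48 to 3.78) and the lowest mean of the PDGF and MAPK list (8.11 against 8.46 to 8.48). Secondary glioma 2 was lowest for Bub1b (5.10 against 5.85 to 5.99) and Tcf7l2 (8.63 against 9.07 to 9.12). The mean of the mesenchymal and extracellular matrix list was lowest in secondary glioma 4 (7.37 against 7.66 to 7.70), and that of the MHC class I list was lowest in secondary glioma 1 (9.16 against 9.56 to 9.59). Groups of 3 were not screened.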

How the results depend on the processing

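Leaving out secondary glioma 3 and tertiary glioma 1 together, leaving out the immune list genes, and the tests of the replicate numbers were chosen after the data were seen. Genes called ranged from 647 to 1857 when 1 sample was left out, those higher from 27 to 781, those lower from 610 to 1076 and those changed by at least 1 on the log2 scale from 616 to 1255. Lists called ranged from 11 to 20 and those higher from 1 to 8. The distance between minus within groups ranged from 0.0660 to 0.0908, with exact p of 0.0667 or 0.1, the smallest that fewer samples allow, and the difference in spread within groups from -0.00518 to 0.0289. Array weights gave 1933 genes, 668 higher. An adjusted p under 0.10 gave 1622, 437 higher. Every probe tested on its own gave 1869, 1647 lower and 1565 changed by at least 1. Per-gene variances gave 210, of which 5 were higher, 205 lower and 196 changed by at least 1, with 2312 genes at an unadjusted p under 0.05. A filter at the 50th percentile left 2 lists higher, fry left 1, and an estimated correlation left 0 lists, 0 higher and 0 lower. Without both secondary glioma 3 and tertiary glioma 1 there were 543 genes higher, 8 lists higher and a distance of 0.0831 (exact p = 0.1, the smallest possible there). Without the immune list genes 955 were called, 818 lower. The cause was not tested.

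With the replicate number as a block, 636 genes were called, 61 higher and 575 lower. Number 4 occurs only among secondary gliomas, so secondary glioma 4 added nothing to the log2 fold changes of that fit. Deviations of samples sharing a number correlated at 0.04, -0.14 and 0.01, and no sample correlated best with the one sharing its number. The numbers were therefore not taken to pair the samples.

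Genes that had not passed changed sign in 13 cases. Cspg4 was at -0.0906 with array weights and -0.31 without both samples, and ranged from -0.16 to 0.39 with 1 sample left out. Pdgfra was at -0.0270 and -0.0883 under the same settings and ranged from -0.0226 to 0.10. Olig2 was at -0.13 without both and ranged from -0.0469 to 0.28, Gfap from -0.70 to 0.0324 and Mki67 from -0.0842 to 0.96. Of the named genes that passed, none changed sign, with 1161 calls kept and 152 lost over the alternatives, and 53 of 83 genes kept their call under each of them. Called lists kept 237 calls and lost 32. Signal over background limits the falls, since the tertiary mean lay below the dim filter in 108 genes called lower, whose fold changes depend on values near background.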

Other observations

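Gene families outside the fixed lists, the synthetase lists and all tests of the myeloid and higher genes were chosen after the results were seen. The chromosome pattern and its 2 sample and chromosome pairs were also picked from the data, but their 3 tests were written before their results. Of all genes tested 6.33% were called lower in tertiary gliomas, and many genes of innate immune families were among them, in the samples where the microglia and macrophage markers had a median log2 fold change of -4.19. Fisher's exact tests of the 14 families were run but carry no weight and are not given, since the families were picked after the calls were seen and their genes move together. Of 11 cathepsins, the lysosomal proteases, 10 were lower, with Ctsh at -4.75 ± 0.27 (log2 fold change ± SE), Ctsz at -3.72 ± 0.24 and Ctsd at -2.49 ± 0.17. Of 10 toll-like receptors 7 were lower, with Tlr2 at -4.30 ± 0.37, Tlr13 at -3.94 ± 0.32 and Tlr7 at -3.30 ± 0.26. Of 6 Fc receptors 5 were lower, with Fcgr3 at -4.42 ± 0.40 and Fcgr1 at -4.36 ± 0.29. So were 5 of 8 Ms4a genes, 3 of 5 Siglec genes and 3 of 6 Schlafen genes, with Slfn5 at -4.68 ± 0.22 and Slfn2 at -2.98 ± 0.15. Of 13 C-type lectins 4 were lower, as were 4 of 13 purinergic receptors. Of 32 collagens 4 were higher and 1 lower, and of 68 potassium channels 3 were lower. No gene among 33 kinesins, 32 protocadherins, 12 Hox genes and 4 olfactory receptors was called by limma. All 10 genes named with values here kept their call when any 1 sample was left out.

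Some cytosolic enzymes that load amino acids onto tRNA were higher, and these lists were not tested against all other genes. Of 11 cytosolic synthetases listed as targets of the stress transcription factor ATF4, 7 rose: Lars by 1.28 ± 0.24, Wars by 1.14 ± 0.19, Gars by 1.01 ± 0.20, Tars by 0.93 ± 0.22, Eprs by 0.92 ± 0.21, Sars by 0.80 ± 0.15 and Iars by 0.67 ± 0.16. Of 6 other cytosolic synthetases only Kars passed (0.95 ± 0.21), while 5 of the 6 were positive, with Rars at 1.01 ± 0.28 (adjusted p = 0.0722), Farsb at 0.66 ± 0.28 and Qars at -0.37 ± 0.23, and of 15 mitochondrial synthetases none did (median 0.12), with Wars2 at -0.59 ± 0.27. Of 11 serine and one-carbon enzymes 2 rose, Mthfd2 by 1.63 ± 0.33 and Shmt2 by 1.57 ± 0.31, while Atf4 had a log2 fold change of 0.04 ± 0.13. Wars kept its call when any 1 sample was left out. Without tertiary glioma 2 the adjusted p was 0.0736 for Lars, 0.0901 for Gars, 0.163 for Tars, 0.135 for Eprs, 0.0703 for Sars, 0.133 for Iars, 0.114 for Kars, 0.0924 for Mthfd2 and 0.0867 for Shmt2. Without tertiary glioma 3 it was 0.0639 for Lars, 0.0777 for Gars, 0.126 for Tars, 0.0908 for Eprs, 0.130 for Iars, 0.106 for Kars, 0.102 for Mthfd2 and 0.0932 for Shmt2. Without secondary glioma 1 it was 0.0814 for Tars, 0.0885 for Eprs, 0.0591 for Iars, 0.0805 for Kars, 0.0618 for Mthfd2 and 0.0568 for Shmt2. It was 0.0657 for Tars, 0.0774 for Iars and 0.0761 for Kars without secondary glioma 2, and 0.0836 for Eprs, 0.0816 for Kars and 0.0579 for Mthfd2 without secondary glioma 3. Without secondary glioma 4 it was 0.0538 for Gars, 0.0799 for Tars, 0.0824 for Eprs, 0.103 for Iars and 0.0633 for Mthfd2, and without tertiary glioma 1 it was 0.0671 for Iars.

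The lower myeloid genes may come from myeloid cells among the sorted cells of secondary gliomas, although the gate on EGFP should remove host cells: 19 of 19 microglia and macrophage markers were lower, with a median percentile of 97.7 among genes in secondary and 44.7 in tertiary gliomas, and the most abundant, C1qb, Laptm5 and Csf1r, averaged 12.30, 12.28 and 12.19 in secondary (n = 4) and 9.13, 9.28 and 7.96 in tertiary gliomas (n = 3), and 3 of the 19 are also in the complement list. Scaling of all genes alike could not be tested, since RMA had already equalised the arrays. Precursor markers lay at a similar median level in secondary gliomas (10.3 against 10.7). The lowest of them had a log2 fold change of -0.40, while each myeloid marker fell by at least 1.79. A lower share of glioma cells raising all other cell types alike was examined through 15 endothelial, mural, fibroblast and ependymal markers. These had room to fall as far as the least fallen myeloid marker. Their median was -0.50 (SD 0.76), and 14, all but Ttr, had log2 fold changes above those of all 19 myeloid markers. That argues against an equal rise for these 4 kinds of markers only. Myelinating oligodendrocyte markers were not included, and all 15 of them were negative (median -1.07, Mag and Mog at -2.42). The mural marker Anpep (-1.88) was left out for lack of room. A lower share of glioma cells is thus not excluded. RNA from a female host would carry Xist, which was at most 2.90 in secondary gliomas, below the dim filter. No sample labelled female shows that this probe reads Xist here, so such RNA is not excluded. Of the 35 splits only the real one gave as many lower genes (915 against a highest other of 0). Other splits mix the groups, which widens the spread within each side, so this count cannot exclude chance. Myeloid cells carrying EGFP, free host RNA and a change of the glioma cells themselves stay open and were not tested.

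The genes higher in tertiary gliomas could be a trace of that same admixture, where dilution of glioma RNA would raise the precursor markers alike. Their median was 0.0725 with an upper quartile of 0.18. The lowest called rise was 0.48, but the threshold for a call sets that value, so setting it against the quartile does not exclude dilution. A fall of the precursor markers in the glioma cells could also hide dilution, and was not tested. Of 35 splits only the real one gave as many (151 against a highest other of 0). Other splits mix the groups, which widens the spread within each side, so this count cannot exclude chance. Of the genes called higher, 7 kept their call in every fit that left out 1 sample. A selective rise of the synthetases listed as ATF4 targets stays open, as their median exceeded that of the other cytosolic synthetases by 0.33 (permutation p over genes 0.0220). Without Lars and Wars, the largest rises among the targets, the difference was 0.26 (permutation p = 0.122), and such a removal lowers it by construction. Without secondary glioma 3 it was 0.27 (permutation p = 0.0298). These p-values treat genes as independent and do not measure the spread between gliomas. Secondary glioma 3 alone was excluded, since without it the target median was 0.76 against 0.92. Chance was not excluded for the 15 lists called, since 10 of 35 splits gave as many and the highest other gave 17.

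In single tertiary gliomas the genes of a whole chromosome lay higher, among genes not called and with a mean log2 value of at least 6. In tertiary glioma 3 the 450 genes of chromosome 10 were shifted by a median of 0.40 (1.32-fold) and in tertiary glioma 2 the 532 genes of chromosome 1 by 0.35 (1.28-fold), while the largest shift of any other sample and chromosome was 0.11. Above the median of other chromosomes lay 84.4% of these chromosome 10 genes in tertiary glioma 3 and 76.5% of the chromosome 1 genes in tertiary glioma 2. Such shares could hardly come out low, since the pairs were picked by their raised medians. They are thus no separate test of a shift, nor of a few strongly raised genes as its source. An intensity effect was excluded by random sets matched on expression, which reached at most 0.0781 in 10000 draws. A candidate explanation, with DNA not analysed here, is gain of a chromosome copy in those tumours, as each of 3 parts of both chromosomes was raised, the lowest by 0.29.

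The red blood cell and sex-linked lists were too short to test. Hba-a2 averaged 9.83 ± 0.06 (SD, n = 4) in secondary and 10.00 ± 0.49 (n = 3) in tertiary gliomas, and Alas2 4.55 ± 0.34 and 4.95 ± 0.29. The Y-linked gene Kdm5d averaged 8.62 ± 0.18 and 8.57 ± 0.15, and Xist lay at 4.86 in tertiary glioma 2 and at or below 2.90 in the other 6 samples. En2 and Cnpy1, both among the largest rises, are neighbours on chromosome 5 with 0 protein-coding genes between them in the gene table.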
